A study of Mus musculus with 6 samples.

How the data were processed

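Small RNA from mouse primary oligodendrocytes and from the extracellular vesicles (EVs) that they released was measured by sequencing, in 3 EV libraries and 3 cell libraries. Per the labels, the oligodendrocytes came from C57BL/6N mice at embryonic day 14 and were grown in Sato medium with 1% horse serum. They were washed, and vesicles were then collected over 24 h in serum-free Sato medium with B27, a supplement for neural cultures. The EV samples were taken at 5 to 6 days in vitro and the cell samples at 6 days. Vesicles were pelleted by spins at 130 g for 10 min, 10000 g for 30 min and 100000 g for 2 h. RNA of 15 to 200 nt was cut from a gel, ligated to adapters with 4 random bases in each, amplified over 14 PCR cycles, selected as libraries of 140 to 300 bp and read for 51 cycles. A 100000 g pellet also holds particles other than vesicles. The labels do not say whether the random bases were used to remove PCR duplicates.

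The authors deposited counts, whole numbers of reads per mature miRNA, in 1 table per sample, with 1906 miRNAs in each table. Per the submitters' processing notes, bcl2fastq 1.8.4, cutadapt 1.7.1, Bowtie 0.12.8 and featureCounts 1.4.6-p4 of the Subread package were used with the mouse build NCBIM37 (mm9). Their settings, the rule for reads that match several places, the use of strand and the miRNA annotation release are not given in the sources used here. Near-identical family members, such as those of let-7, and miRNAs with several genomic copies could therefore share or lose reads. The gene table used here to see which miRNA genes neighbour each other belongs to another build, so no coordinates are given.

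Groups and replicate numbers came from the labels. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Total counts were 431004, 313766 and 689475 in the EV libraries and 156189, 126910 and 202358 in the cell libraries. One read was worth between 1.45 and 3.19 CPM (reads scaled to a common library total) in the EV libraries and between 4.94 and 7.88 CPM in the cell libraries. A count of 0 allows up to 3 reads, which is 4.35 to 9.56 CPM in an EV library and 14.8 to 23.6 CPM in a cell library. Counting intervals and these floors cover counting error only. Within each group, chi-square statistics of the counts were 7.73 to 37.5 times their degrees of freedom, so no 2 libraries differed by as little as sampling noise.

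The comparison of EVs with cells used edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided, R 4.3.3) on the deposited counts. Normalization was by trimmed mean of M-values (TMM) after filterByExpr at its minimum count of 10, with group as the only term. P-values were adjusted by Benjamini-Hochberg (BH) over the 336 miRNAs kept, and a miRNA was called at an adjusted p below 0.05. Fold changes are EVs over cells. CPM values were computed from the total counts, without the TMM factor. The standard error was derived from the fitted coefficient and the F statistic. The biological coefficient of variation was 23.8%.

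A total of 15 miRNA lists was fixed from general knowledge before the data were examined, together with the tests, the main design and most alternatives. They covered the oligodendrocyte lineage, neurons, astrocytes, microglia, erythroid cells and blood, liver, striated muscle, epithelium, endothelium with fibroblasts, the let-7 family, the miR-17~92 clusters, the miR-183 cluster, the Dlk1-Dio3 locus, the Sfmbt2 cluster, and miRNAs reported in EV or Argonaute-bound serum RNA. Lists with at least 3 tested members, 12 of the 15, were tested with camera (limma 3.58.1, preset correlation 0.01) against all other tested miRNAs. The proportion of the 5p and 3p arms of a hairpin was tested with limma on log2((5p + 0.5)/(3p + 0.5)), for hairpins with at least 10 counts over both arms in every library. Reads of genomic copies that share a number and letter, such as those of let-7f and miR-138, were summed per arm. A tested hairpin can therefore stand for several loci, and its ratio may also shift with the mix of copies. Library measures were compared by exact permutation tests, which with 3 against 3 cannot give a p below 0.1.

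The named miRNAs were the 10 most abundant of each group, and the 12 largest increases and 12 largest decreases among called miRNAs with a mean of at least 100 CPM and no overlap between groups. Copies with the same mature sequence counted once. The 4 most abundant members of each list and the 5 largest arm changes in each direction were added. Any miRNA outside this rule is said to have been chosen after its values were seen.

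Same-numbered EV and cell libraries deviated together from their group means, with correlations over the 336 miRNAs of 0.115, 0.103 and 0.254 on log2 CPM with a prior count of 2. Libraries with different numbers correlated at -0.140 to 0.020, below all same-numbered pairs. Deviations from a group mean cancel within the group, so these values are not independent of the same-numbered ones. The labels do not state a pairing, and the check was borderline: the lowest of the 3 correlations was 0.0975 with a prior count of 0.5, 0.0998 with 1 and 0.1004 with 5, against a limit of 0.1. The main tests did not use the pairing, as group was their only term. A fit with the replicate number as a block is given as an alternative, where it changes the call of a named miRNA or the counts of a list.

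Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, a test against a 2-fold change), the block, leaving out each library, and thinning all libraries to the smallest total. The steps were tested on simulated counts for this comparison. Of 200 miRNAs changed among 336 simulated (324 tested), 67.0% of those changed 2-fold and 100% of those changed 4-fold were called in the right direction, and 2.44% of all calls were false. Of 12 simulated lists the shifted one was recovered, and 0 lists that shared no member with it were called. The simulated miRNAs varied independently, so this could not show false list calls that arise from correlation between miRNAs. In the data the estimated correlation was 0.30 for the Dlk1-Dio3 locus, 0.13 for the let-7 family and 0.11 for the liver list. The arm test found 65% of 40 changed hairpins among 187 and made 18 false calls. With at least 5 counts of each arm in every library it found 12 of 12 changed hairpins among 62 and made 0 false calls. All simulated arm changes were 4-fold, with the same added noise for every hairpin. Smaller changes and hairpins with a larger spread were not simulated. That stricter rule was added after the data were seen. Culture medium without cells was not analysed here.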

Results

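Counts of mature miRNAs were compared between EVs released by mouse primary oligodendrocytes, the myelin-forming cells of the central nervous system, and the oligodendrocytes themselves. There were 3 libraries of each. By its title, the study asked whether supplements of serum-free culture media bring miRNAs that are isolated together with vesicles. Without a library of medium alone, the comparison shows which miRNAs were more or less abundant in the vesicle pellet than in the cells, not where they came from.

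miR-9-5p, a miRNA of neural cells, was the most abundant miRNA in all 6 libraries, and the EV libraries were less dominated by it than the cell libraries. It held 10.2% ± 2.07 of counts in EVs and 17.95% ± 1.35 in cells (mean ± SD, n = 3 each). The 10 most abundant miRNAs together held 42.9% ± 2.12 in EVs and 53.5% ± 2.62 in cells. For both measures the exact permutation p was 0.1, two-sided, the smallest that 3 against 3 allows. EV libraries held 399 ± 44.1 miRNAs with at least 10 counts and cell libraries 278 ± 19.6 (exact permutation p = 0.1), but the EV libraries were deeper, with 313766 to 689475 counts against 126910 to 202358. After thinning to 126910 counts each, the numbers were 285 ± 7.23 and 261 ± 6.56 (exact permutation p = 0.1), so the difference fell from 121 to 24.3 miRNAs.

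The vesicle profile followed the cell profile in broad terms. Across 336 miRNAs, which are not independent replicates, the group means of log2 CPM had a Pearson r of 0.878 and a Spearman rho of 0.858. Single EV and cell libraries correlated at 0.846 to 0.879, below the lowest values within EVs (0.979) and within cells (0.954). miR-128-3p, a neuronal miRNA, was the next most abundant in EVs at 78840 ± 11200 CPM, against 31370 ± 11300 CPM in cells. miR-181a-5p followed at 38800 ± 2760 CPM in EVs and 44160 ± 1160 CPM in cells.

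**Figure D1:**
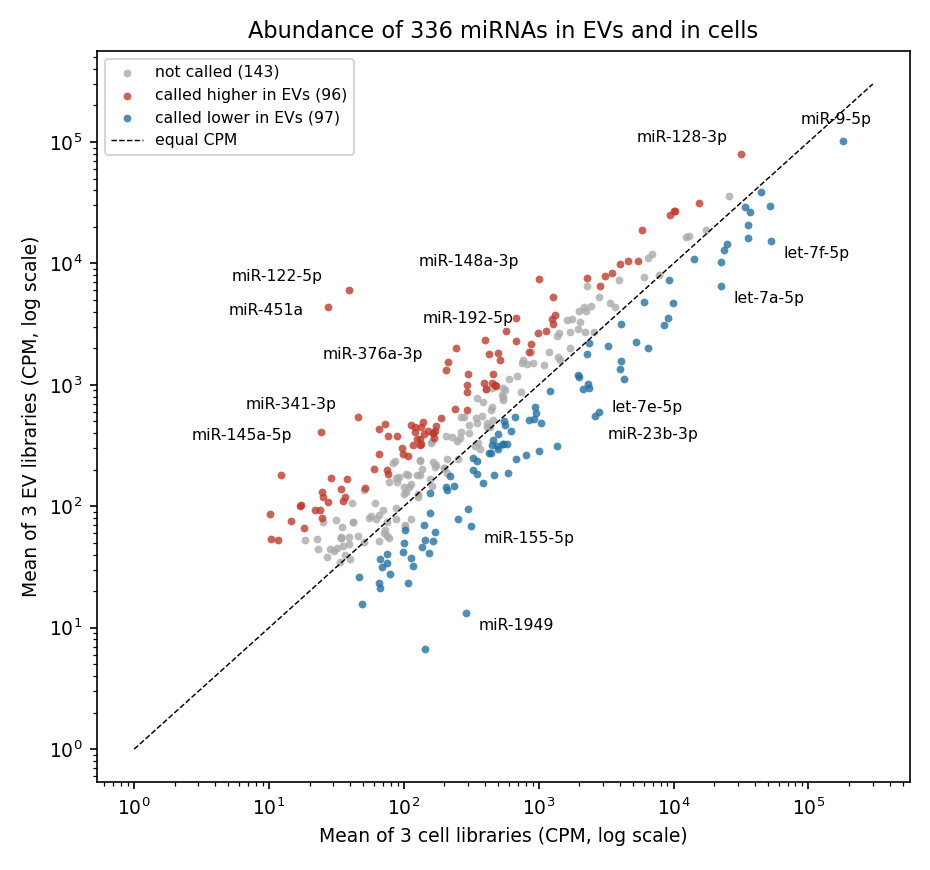
Mean abundance of the 336 tested miRNAs in the 3 cell libraries (x axis, CPM, log scale) and in the 3 EV libraries (y axis, CPM, log scale), coloured by the result of the edgeR test, with a dashed line at equal CPM. miR-122-5p and miR-451a lie far above the line, at 6074 and 4368 CPM in EVs and 38.9 and 27.6 CPM in cells, and let-7a-5p, let-7e-5p, let-7f-5p and miR-1949 lie below it.

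The largest increases in EVs belonged to 2 miRNAs of other tissues. miR-122-5p, the dominant miRNA of hepatocytes, stood at 6074 ± 2090 CPM in EVs and 38.9 ± 12.4 CPM in cells. miR-451a, a miRNA of red blood cells, stood at 4368 ± 1570 CPM in EVs and 27.6 ± 23.9 CPM in cells. By edgeR's quasi-likelihood test with BH adjustment, the log2 fold changes were 6.84 (SE 0.37, adjusted p = 2.58e-06) and 6.97 (SE 0.50, adjusted p = 1.19e-05), and each EV library exceeded each cell library. The cell values rested on 18 reads of miR-122-5p and 12 of miR-451a over the 3 libraries, against 9511 and 5880 reads in EVs. With reads and totals pooled over the 3 libraries of a group, their shares of reads were 179 (95% exact binomial interval of counting error, 113 to 302) and 166 (94.9 to 321) times as high in EVs. For miR-451a, 7 of the 12 cell reads came from Cells replicate 2, and without that library its log2 fold change was 7.77 and the ratio of pooled shares 294.

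Further named increases were smaller. miR-145a-5p, a miRNA of smooth muscle and mesenchymal cells, rose by a log2 fold change of 3.57 (SE 0.32), miR-341-3p by 3.06 (SE 0.32), miR-376a-3p by 2.58 (SE 0.24), miR-148a-3p by 2.41 (SE 0.21) and miR-136-3p by 2.40 (SE 0.26), with edgeR BH-adjusted p-values of 2.36e-05 to 9.46e-05. miR-497a-5p (2.25), miR-486a-5p (2.20), miR-192-5p (2.07), miR-301a-3p (1.94) and miR-3085-3p (1.83) also rose, with SEs of 0.23 to 0.31 and edgeR BH-adjusted p-values of 9.46e-05 to 0.000938. miR-486b-5p, which has the same mature sequence as miR-486a-5p, rose by 2.22, and the reads of the pair cannot be separated.

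**Figure D2:**
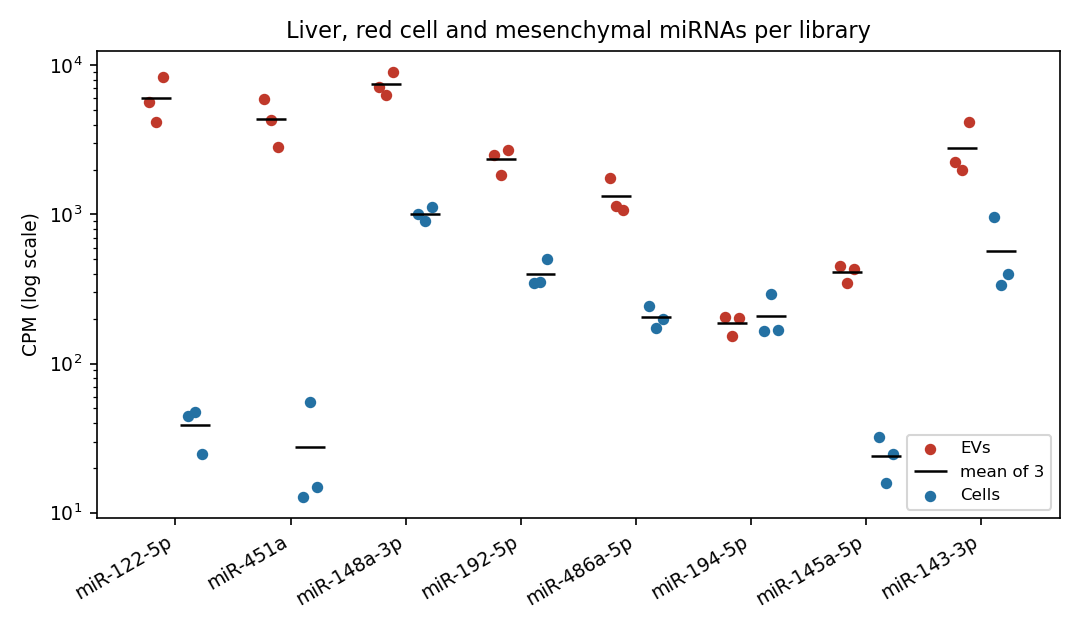
CPM (log scale) of 8 miRNAs of liver, red cells or mesenchymal cells in each EV library and each cell library, with a bar at the mean of 3. miR-122-5p, miR-451a, miR-148a-3p, miR-192-5p, miR-486a-5p, miR-145a-5p and miR-143-3p are higher in every EV library than in every cell library, and miR-194-5p overlaps between the groups.

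The largest decrease was that of miR-1949, at 13.2 ± 7.61 CPM in EVs and 288 ± 46.3 CPM in cells, a log2 fold change of -4.90 (SE 0.41, edgeR BH-adjusted p = 2.36e-05) that rested on 19 reads in EVs. let-7e-5p (-2.71), miR-23b-3p (-2.70), miR-340-3p (-2.61), let-7a-5p (-2.27), let-7f-5p (-2.26) and let-7d-5p (-2.16) followed, with SEs of 0.16 to 0.30 and edgeR BH-adjusted p-values of 1.15e-05 to 0.000103. miR-155-5p, which is induced in activated myeloid cells, had a log2 fold change of -2.66 (SE 0.57, edgeR BH-adjusted p = 0.00341), with 19.1 to 125 CPM in EVs and 173 to 568 CPM in cells. miR-5099 (-2.47), miR-6239 (-2.32), miR-330-5p (-2.15) and miR-130b-5p (-2.15) were also lower, with SEs of 0.30 to 0.44 and edgeR BH-adjusted p-values of 0.000348 to 0.00144.

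Among the most abundant miRNAs, miR-9-5p fell by 1.28 on the log2 scale (SE 0.21), miR-21a-5p by 1.65 (SE 0.25) and miR-26a-5p by 1.23 (SE 0.15), with edgeR BH-adjusted p-values of 0.000207 to 0.00087. miR-30e-5p rose by 0.93 (SE 0.16, adjusted p = 0.0012) and miR-101a-3p by 0.98 (SE 0.18, adjusted p = 0.00203). miR-181a-5p (-0.66) and miR-181b-5p (-0.68) were lower with TMM, but with library size only their log2 fold changes were -0.19 and -0.21 and neither was called. miR-128-3p rose by 0.84 (SE 0.30, edgeR BH-adjusted p = 0.0348). Its call ended without EVs replicate 1 (0.85, adjusted p = 0.0636), EVs replicate 2 (0.60, 0.132), Cells replicate 2 (0.60, 0.0888) or Cells replicate 3 (0.71, 0.125).

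In total, 96 of 336 miRNAs were called higher and 97 lower in EVs. Of these, 58 and 76 differed at least 2-fold, and 16 and 24 at least 4-fold. The CPM values of the groups, which carry no TMM factor, did not overlap for 227 miRNAs (67.6%). For a single miRNA chance gives 10% with 3 against 3, but these miRNAs share the same 6 libraries. For 159 of the tested miRNAs (47.3%) every EV library lay above every cell library, so this count leans towards EVs where the TMM calls do not. The balance of directions depended on the scaling: with library size only, 71.2% of called miRNAs were higher in EVs and 60 were lower, in place of 49.7% higher, and the median log2 fold change of all tested miRNAs was 0.54 in place of 0.06. A direction for a miRNA with a small fold change is therefore relative to the TMM scaling.

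The question of which tissues and clusters these miRNAs belong to was addressed with the lists. The liver list, the let-7 family and the Dlk1-Dio3 locus were called by camera, and the other 9 tested lists were not. None of the 3 calls held with a correlation estimated from the data, in a design with 4 residual degrees of freedom.

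In the liver list, 3 of 5 tested members rose and 0 fell, with a median log2 fold change of 2.07 (camera BH-adjusted p = 0.00268, and adjusted p = 0.342 with an estimated correlation). The same 3 and 0 were found adjusted over the list alone. The members that rose were miR-122-5p, miR-148a-3p (7493 ± 1380 CPM against 1009 ± 105) and miR-192-5p (2343 ± 441 CPM against 399.8 ± 86.1). miR-194-5p, which has a gene copy beside that of miR-192, stood at 186 ± 28.8 and 209 ± 71.8 CPM (log2 fold change -0.60, edgeR BH-adjusted p = 0.0716). miR-148a and miR-192 are not confined to liver, and without miR-122-5p the list's median was 1.19 (camera BH-adjusted p = 0.112), so this call rested on miR-122-5p. The median of the list was 1.39 without Cells replicate 1.

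In the erythroid and blood list, 6 of 14 members rose and 2 fell, also adjusted over the list alone, with a median of 0.43 (camera BH-adjusted p = 0.139, not called). Without a filter beyond a count above 0, camera called the list higher (median 0.59, BH-adjusted p = 0.00504). So did fry, which does not compare a list with other miRNAs (BH-adjusted p = 0.00215). The tested arms of miR-106b, miR-25, miR-92a and miR-93 also belong to the list of paralogous clusters given below. They include both falls and the rises of miR-106b-5p, miR-93-3p and miR-93-5p. miR-451a and miR-486a-5p rose, while miR-92a-3p (-0.04), miR-16-5p (-0.41) and miR-25-3p (0.42), which many cell types express, did not pass the test. This depended on the method for miR-25-3p, which was called higher with library size only (0.89, edgeR BH-adjusted p = 0.00128), DESeq2 (0.36, 0.047), limma-voom (0.42, 0.0382) or the 10 CPM filter (0.46, 0.0329), and without Cells replicate 1 (0.47, 0.0292). miR-92a-3p was called higher with library size only (0.42, 0.0297) and miR-16-5p lower without Cells replicate 1 (-0.64, 0.0138). miR-93-5p (0.46, edgeR BH-adjusted p = 0.0351) was not called with the replicate number as a block (adjusted p = 0.0692) or without any of 5 single libraries (0.39 to 0.48), Cells replicate 1 being the exception. Its call also ended with upper-quartile scaling (0.35, adjusted p = 0.108) and after thinning (0.45, 0.0808). With the block 4 members rose and 2 fell, and with library size only 10 rose and 1 fell.

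The let-7 family, which rises as cells differentiate, was lower in EVs. Of 18 tested members 10 fell and 1 rose, with a median of -1.08 (camera BH-adjusted p = 0.00268, and adjusted p = 0.342 with an estimated correlation). Adjusted over the list alone, 10 fell and 2 rose. let-7c-5p fell by 1.29 on the log2 scale (SE 0.17), let-7i-5p by 1.25 (SE 0.16) and let-7b-5p by 0.97 (SE 0.20). The 11 members that are 5p arms or have no arm in their name held 11.3% ± 2.08 of counts in EVs and 21.4% ± 0.32 in cells, and their sum fell by 1.45 on the log2 scale (SE 0.15, edgeR BH-adjusted p = 0.000111). let-7g-5p, chosen after its values were seen, stood apart from its relatives at 16850 ± 2290 CPM in EVs and 12940 ± 2920 CPM in cells, with a log2 fold change of -0.07 (SE 0.17), or 0.38 with library size only, called in neither. let-7k, also chosen after its values were seen, did not fall either (0.04, SE 0.64, edgeR BH-adjusted p = 0.971). It stood at 38.2 ± 8.93 CPM in EVs and 26.8 ± 26.9 CPM in cells, but rested on few reads. The member that rose, let-7a-1-3p (0.96, edgeR BH-adjusted p = 0.0348, chosen after its values were seen), is a passenger strand, and with the replicate number as a block, or after thinning, 0 members rose and 9 fell. With library size only, 5 rose and 9 fell. Members that share a sequence or differ by few bases could have exchanged reads, so the members counted may not all be distinct sequences.

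**Figure D3:**
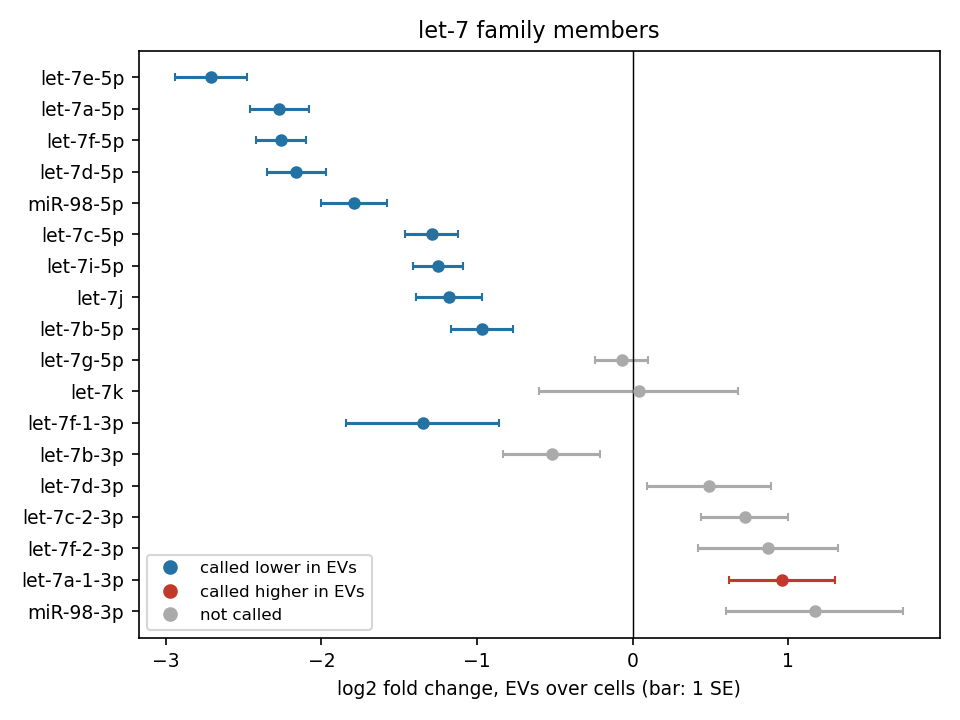
Log2 fold change of EVs over cells for 18 let-7 family members from the edgeR fit with TMM scaling, with a bar of 1 SE on each side, 5p or unnamed arms above 3p arms. Most 5p members lie between -2.71 and -0.97, while let-7g-5p lies at -0.07, or at 0.38 with library size only, and the sparse let-7k at 0.04 with an SE of 0.64.

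miRNAs of the Dlk1-Dio3 locus, a large imprinted cluster active in brain and embryo, were mostly higher in EVs. Of 44 tested members 25 rose and 3 fell, with a median of 0.85 (camera BH-adjusted p = 0.000767, and adjusted p = 0.597 with an estimated correlation). Adjusted over the list alone, 28 rose and 3 fell. miR-341-3p, miR-376a-3p, miR-136-3p and miR-369-3p (1.43, SE 0.26) rose. miR-434-3p (0.85) and miR-127-3p (0.83, edgeR BH-adjusted p = 0.0357) were called by a smaller margin. The call of miR-127-3p ended with the replicate number as a block (0.80, adjusted p = 0.0541) and without EVs replicate 2 (0.41), Cells replicate 2 (0.76) or Cells replicate 3 (0.69), and that of miR-434-3p without EVs replicate 1 (0.76), EVs replicate 2 (0.64) or Cells replicate 3 (0.73). After thinning neither was called (0.74, adjusted p = 0.0789, and 0.68, adjusted p = 0.064), and without the most abundant miRNA miR-127-3p was not (0.74, adjusted p = 0.051). The number that rose was 27 with the block, 16 without EVs replicate 1 and 16 without EVs replicate 2, where 41 and 39 members were tested, and 16 of 32 tested after thinning.

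In the oligodendrocyte lineage list, 5 of 16 members rose and 7 fell, or 5 and 8 adjusted over the list alone, with a median of -0.52 (camera BH-adjusted p = 0.424). miR-219a-2-3p and miR-338-5p, from hairpins that promote oligodendrocyte differentiation, fell by 1.37 (SE 0.23) and 2.06 (SE 0.21) on the log2 scale, while miR-138-5p rose by 0.73 (SE 0.17), with edgeR BH-adjusted p-values of 6.81e-05 to 0.00482. With library size only, 5 members rose and 4 fell, and with the block 4 rose and 7 fell. miR-219a-5p rose by 0.81 (SE 0.26, edgeR BH-adjusted p = 0.026), but not with the replicate number as a block (0.75, adjusted p = 0.0535), nor without EVs replicate 2 (0.39), Cells replicate 2 (0.70) or Cells replicate 3 (0.78).

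The neuron list went both ways, with 7 of 22 members higher and 6 lower, also adjusted over the list alone (camera BH-adjusted p = 0.852). Its median was 0.05, while its mean was -0.10 and the test's direction was down. miR-9-5p fell. miR-9-3p stood at 0.04, or at 0.48 and called with library size only (edgeR BH-adjusted p = 0.0419). miR-124-3p, a neuron-specific miRNA, rose by 0.97 (SE 0.25, edgeR BH-adjusted p = 0.00832), a call that ended without EVs replicate 1 (0.85, adjusted p = 0.0636) or EVs replicate 2 (0.74, 0.0846). The number of higher members fell to 6 with the replicate number as a block, 2 without EVs replicate 1, 3 without EVs replicate 2 and 3 without Cells replicate 3. The cell libraries also held 4477 reads of the miR-124 3p arm, and whether the cultures held neurons or other cells was not assessed here.

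In the astrocyte list, 5 of 10 members rose and 2 fell, also adjusted over the list alone (median 0.40, camera BH-adjusted p = 0.424). The median was 0.24 without Cells replicate 2, 0.86 without Cells replicate 1 and 0.72 to 0.81 without an EV library. miR-143-3p (1.76, SE 0.45), which shares a gene neighbourhood with miR-145a, and miR-29a-3p (0.86, SE 0.21) rose, and miR-26a-5p fell. The largest rise of the list was that of miR-145a-5p (3.57), described above as a miRNA of smooth muscle and mesenchymal cells. The 5 rises can therefore not be read as astrocyte miRNAs alone. When a library was left out, miR-143-3p lay between 1.41 and 2.49. In the endothelial and fibroblast list, 3 of 8 rose and 1 fell, also adjusted over the list alone (median 0.53, or 0.98 without EVs replicate 2, camera BH-adjusted p = 0.424). The reads of miR-199a-3p and miR-199b-3p (the latter chosen after its values were seen), which share a mature sequence, cannot be separated. The 3 that rose are therefore 2 distinct sequences. miR-126a-5p rose by 1.53 (SE 0.34) and miR-199a-3p by 2.01 (SE 0.43), the latter not called after thinning (1.59, edgeR BH-adjusted p = 0.0548).

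Of the microglia and myeloid list, 0 of 7 members rose and 4 fell, or 1 and 4 adjusted over the list alone (median -1.01, camera BH-adjusted p = 0.369). miR-155-5p kept its call in each alternative run, at -3.39 to -1.98 when a library was left out. By contrast, miR-146a-5p (-1.71) and miR-142a-3p (-1.19) lost theirs with library size only (-1.18 and -0.73). The number of lower members fell to 1 without Cells replicate 3, where the median was -0.61 and miR-146a-5p (-1.50) and miR-142a-3p (-0.80) were not called, and to 2 without Cells replicate 1, where miR-146a-5p stood at -1.47. After thinning 2 of 6 tested members were lower, and miR-142a-3p was not called (-0.87, adjusted p = 0.134). miR-342-3p, the most abundant member, went the other way (0.46, edgeR BH-adjusted p = 0.0545, not called) and was called higher with library size only (0.92, 0.00217), without a filter (0.60, 0.0443), with the 10 CPM filter (0.50, 0.0396), with limma-voom (0.45, 0.0441) and without EVs replicate 3 (0.50, 0.0474). With library size only, 1 member rose and 1 fell.

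Of the miR-17~92 and paralogous clusters, 8 of 15 members rose and 3 fell, or 9 and 3 adjusted over the list alone (median 0.46, camera BH-adjusted p = 0.366). With the block 7 rose and 3 fell. miR-19b-3p rose by 1.29 (SE 0.26). All 3 tested members of the Sfmbt2 cluster fell, also adjusted over the list alone (median -1.87, camera BH-adjusted p = 0.112), with miR-669c-5p at -1.85 and miR-669a-5p at -1.87. Without Cells replicate 3 the call of miR-467e-5p ended (-1.51, edgeR BH-adjusted p = 0.081), without any 1 EV library 2 members were tested, and after thinning 1 was. The list of miRNAs reported in EV or Argonaute-bound serum RNA did not stand apart, with 4 of 16 higher and 4 lower, also adjusted over the list alone (median -0.10, mean 0.61, test direction up, camera BH-adjusted p = 0.369), or 7 and 2 with library size only and 3 and 4 with the block. Striated muscle (2 tested, both lower, also adjusted over the list alone), epithelial (1 tested, 0 called) and miR-183 cluster (2 tested, 0 called) miRNAs were too few to test as lists. Of the miR-183 cluster, miR-182-5p was called higher with library size only (0.81, edgeR BH-adjusted p = 0.0495). miR-206-3p, a miRNA of skeletal muscle, fell by 2.11 on the log2 scale (SE 0.46, edgeR BH-adjusted p = 0.00369), and lay between -2.78 and -1.80 when a library was left out. miR-1a-3p stood at -1.78, or at -1.28 and not called with library size only. Its call also ended without EVs replicate 1 (-1.62, adjusted p = 0.0609), Cells replicate 1 (-1.49, 0.0954) or Cells replicate 2 (-1.85, 0.0511).

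**Figure D4:**
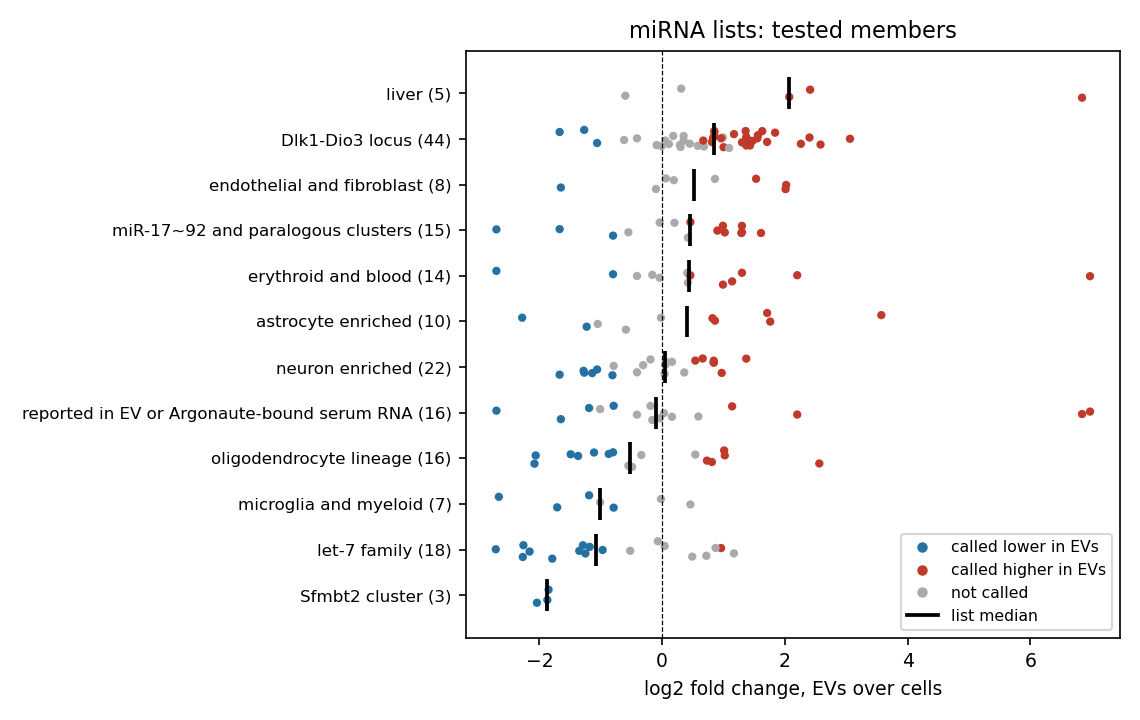
Log2 fold changes of EVs over cells (x axis, TMM scaling) for the tested members of 12 miRNA lists, with the number tested in brackets, coloured by the edgeR result and with a bar at the list median. The liver and Dlk1-Dio3 medians lie at 2.07 and 0.85, those of the let-7 family and the Sfmbt2 cluster at -1.08 and -1.87. The neuron and serum RNA medians, 0.05 and -0.10, change sign with the scaling.

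Whether the 2 arms of a hairpin were present in the same proportion in vesicles and cells does not depend on the scaling between libraries. For miR-340 the 5p arm gained on the 3p arm in EVs, with a log2 ratio of 4.63 ± 0.19 in EVs and 2.15 ± 0.33 in cells, a difference of 2.48 (SE 0.38, limma BH-adjusted p = 0.00166). For let-7a, with reads of its genomic copies summed, the 5p arm lost. Its log2 ratio was 4.05 ± 0.47 in EVs and 7.29 ± 0.52 in cells, a difference of -3.24 (SE 0.47, limma BH-adjusted p = 0.00142). The planned test called 69 of 187 hairpins, 24 with a higher and 45 with a lower share of the 5p arm in EVs. The number fell to 13 after thinning, to 27 without EVs replicate 1 and to 42 without EVs replicate 3. It includes 44 hairpins with fewer than 5 counts of an arm in some library, 6 of them with an arm at 0 in all 6 libraries, where the ratio follows depth. Of the 5 largest changes in each direction, only miR-340 and let-7a had at least 5 counts of each arm in every library. The other 8 were miR-32, miR-486a, miR-30b and miR-346 on the 5p side, and miR-381, miR-500, miR-137 and miR-874 on the 3p side. Outside these, miR-130b, miR-212, miR-301a and let-7d, chosen after their values were seen, also had at least 5 counts of each arm. Their differences of -3.22 to -2.76 were larger in size than that of miR-340. With at least 5 counts of each arm, a rule added after the data were seen, 28 of 67 hairpins were called, 10 with a higher and 18 with a lower 5p share, and 25 of them were also among the 69.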

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

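Thinning of the detection counts was planned, while thinning before the edgeR and arm tests, the rule of 5 counts of each arm, and the lists without miR-122-5p and miR-451a were chosen after the data were seen. Of 1476 values of single miRNAs, lists and hairpins under alternatives, 1330 kept their direction and their side of the threshold, 93 lost a call, 19 gained one and 34 changed sign, 0 of these among called results. Leaving out 1 library ended the call of 12 named miRNAs and 2 named hairpins in at least 1 case. Among the miRNAs named by the rule, the block ended the calls of miR-93-5p, miR-127-3p and miR-219a-5p, and its effect on the members of each list is given with the lists. The cause of the changes below was not tested unless stated.

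The number of called miRNAs (96 higher, 97 lower) was 91 and 96 with the replicate block, 89 and 99 with DESeq2 and 98 and 98 with limma-voom, and 66 to 101 and 88 to 98 when a library was left out. In all 125 were called after thinning (60 higher, 65 lower), where 271 miRNAs were tested, and 57 against a 2-fold change (37 lower). The share higher, 49.7% of calls, was 71.2% with library size only, where 60 were lower, 35.1% against a 2-fold change, and 41% to 50.8% when a library was left out. The number of called lists (3) was 0 with an estimated correlation and 7 with fry, which does not compare a list with other miRNAs. The number of called hairpins (69) was 76 with the replicate block, 43 with at least 50 counts, 28 with at least 5 counts of each arm, 13 after thinning, and 27 to 67 when a library was left out. The difference in miRNAs with at least 10 counts (121) was 24.3 after thinning. The Pearson and Spearman correlations were 0.909 and 0.882 with the 10 CPM filter, and 0.866 to 0.889 and 0.842 to 0.869 when a library was left out.

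miR-9-3p (0.04) was at -0.03 with DESeq2 and with its size factors, -0.10 with upper-quartile scaling, -0.08 without the most abundant miRNA, and -0.13 to 0.19 when a library was left out. miR-191-5p (0.03) was at -0.03, -0.03, -0.09, -0.07 and -0.08 to 0.08 in the same order. Both were called higher with library size only, miR-9-3p at 0.48 (edgeR BH-adjusted p = 0.0419) and miR-191-5p at 0.50 (0.0397). With library size only, miR-92a-3p was at 0.42, miR-16-5p at 0.03 (from -0.41), miR-203-3p at 0.38, miR-34c-5p at 0.39 and miR-183-5p at 0.37, which the shift of the median accounts for. Without the filter, miR-34c-5p was at 0.05, miR-183-5p at 0.04, miR-92a-3p at 0.10 and miR-203-3p at 0.04. With limma-voom miR-34c-5p was at 0.03, and after thinning miR-182-5p was at -0.19 (from 0.33). When a library was left out, miR-34c-5p lay between -0.47 and 0.62, miR-183-5p between -0.23 and 0.17, and miR-203-3p between -0.30 and 0.02. The test of the neuron list turned up at a median of 0.09 with the 10 CPM filter and 0.20 without a filter. Its direction was also up without the most abundant miRNA, without Cells replicate 1 and without Cells replicate 2. The median was -0.06 without the most abundant miRNA and -0.16 to 0.19 when a library was left out. In cells, 3 reads are 14.8 to 23.6 CPM, so levels below that were not resolved.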

Other observations

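The regroupings of libraries were planned, and the other tests in this part, together with the miRNAs singled out here, were chosen after the results were seen.

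The balance of arms shifted in several hairpins. For miR-219a the 5p arm was at 8310 ± 2400 CPM in EVs and 3473 ± 246 in cells while the 2-3p arm was at 12820 ± 1460 and 23530 ± 5180. The difference in the log2 ratio of arms, with reads of the miR-219a copies summed per arm, was 2.08 (SE 0.40, limma BH-adjusted p = 0.00426). The rise of the 5p arm by itself was not called with the replicate number as a block (0.75, edgeR BH-adjusted p = 0.0535) or without EVs replicate 2 (0.39, adjusted p = 0.112). For miR-106b, miR-106b-5p was at 7624 ± 445 CPM in EVs and 2274 in cells (1511 to 2750), and miR-106b-3p at 396.9 ± 60.9 and 498.9 ± 76.6, a difference of 2.12 (SE 0.40, limma BH-adjusted p = 0.00426), where the groups overlapped for the 3p arm. Of the 28 hairpins called with at least 5 counts of each arm, the arm with more reads over all 6 libraries gained in EVs in 18 and lost in 10. The deeper EV libraries weigh more in that choice of arm. For miR-130b, miR-335 and miR-674, counted as gains, the other arm led in cells. The balance of 18 and 10 therefore depends on this definition. Neighbouring genes did not always move together: miR-143-3p and miR-145a-5p were both higher in EVs, whereas miR-192-5p was higher and miR-194-5p was not called. miR-144, encoded near miR-451a, was sparse, with 79 EV reads and 1 cell read of its 3p arm (26.7-fold between the shares of pooled reads, 95% exact interval 4.66 to 1070) and 59 and 0 reads of its 5p arm.

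Some miRNAs varied widely between replicates. miR-2137 had 6350 CPM in EVs replicate 1 against 1147 and 569 CPM in the other 2 EV libraries, and 1048 to 1818 CPM in cells. miR-146a-5p was lowest in replicate 2 of both groups, at 303 CPM against 1248 and 1504 CPM in EVs, and at 1040 CPM against 2772 and 3148 CPM in cells.

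With 6 libraries there are 10 ways to form 2 groups of 3, too few for a share under 0.05. The real grouping gave 96 higher and 97 lower miRNAs and the highest other 0 in all, so 1 of 10 gave as many. For hairpins the numbers were 69 and 0, again 1 of 10. Every other grouping puts EV and cell libraries into the same group, so the difference between EVs and cells adds to the spread there. The 0 calls of those groupings therefore say little about chance. For lists they were 3 and 3, and 2 of the 10 groupings gave as many. The other grouping with 3 called lists parted 1 same-numbered pair. Of the 3 other groupings that part all 3 pairs, as the real one does, the highest called 2 lists.

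The first pattern is the height of miR-122-5p and miR-451a in EVs. The tables argue against scaling as the cause, since the lower of the 2 log2 fold changes was 6.74 (SE 0.40) over 4 scalings, and against depth, since it was 6.66 (SE 0.38) after thinning. Liver and blood RNA from outside the oligodendrocytes, for example from a medium supplement, may be the source: 6 of 8 further liver or red cell miRNAs were higher in every EV library than in every cell library, but miR-194-5p and miR-802-5p were not. These are 4 of 6 distinct hairpins, as both arms of miR-144 and the inseparable miR-486a-5p and miR-486b-5p are among the 8. Of all tested miRNAs 47.3% met the same condition, and the 8 were picked with values known, so this count gives little support. Whether the cell reads share that source was not settled: on pooled reads the ratio of the 2 miRNAs did not differ between cells and EVs (Fisher's exact p = 0.85, two-sided), but this covers counting error alone, with 18 and 12 cell reads, while the ratio varied from 0.955 to 2.93 between EV libraries. These sources cannot be told apart from selective export by the oligodendrocytes, which was not tested, since no medium without cells was analysed here and counts on the mouse genome do not tell the species.

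The second pattern is the lower level of let-7 5p members in EVs. The tables argue against an exchange of reads between family members as the whole cause, since the sum of 11 members still had a log2 fold change of -1.45 (SE 0.15). Scaling does not remove it either, as the sum was at -0.92 with library size only (edgeR BH-adjusted p = 0.00035). Nor would a few miRNAs from elsewhere that take counts from all others alike leave the sum at -1.45, since TMM scaling removes a shift shared by most miRNAs. This reading of the TMM value was added after a first test of dilution had come out between its bounds of 20% and 80%: with library size only, 71.8% of 78 other miRNAs with at least 1000 CPM in cells lay above the sum by more than 2 SE, at a median of 0.38 for the 78. The share stayed short of the 80% bound, so the test as written decided nothing for the 78 as a whole. For the 56 that lay above the sum, the values argue against material from elsewhere that lowered them as much as let-7. For the rest of the 78 this stays open. Material that carries many other miRNAs and little let-7, and a difference in release, stay open and were not tested, since no medium without cells was analysed here.

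The third pattern is the shift of arm ratios. Among 25 hairpins called in both analyses with at least 5 counts of each arm, 22 kept a difference beyond 2 SE after thinning, which argues against depth as the whole cause for this part. By the stricter limma BH threshold 9 of the 25 stayed called, among 13 hairpins called after thinning in all. The median absolute difference of the 25 was 1.93 (median SE 0.41) before and 2.02 (median SE 0.53) after thinning, so the differences stayed. The 2 SEs are not comparable. The fit behind the SE and the 2 SE rule after thinning took in all 776 pairs of arms, also empty ones. The fit before thinning took in the 187 tested hairpins, and limma shares information on the spread among the hairpins fitted. Among 44 called hairpins with an arm under 5 counts in some library, 24 kept a difference beyond 2 SE by the same rule. There depth cannot be told apart from a true shift, the counts being too few. For the deeper hairpins, a difference in which arm leaves the cell and a ligation or PCR bias that differs between groups both stay open and were not tested. Where genomic copies were summed, a change in the mix of copies also stays open and was not tested.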
